A study of Oryza sativa with 4 samples.

How the data were processed

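Suspension-cultured cells of rice (Oryza sativa, cultivar Nipponbare), grown in the dark in a modified N-6 medium, were compared in a vector control line and in a line carrying an RNA interference construct against OsCERK1. Per the labels, 40 mg of cells in 1 ml of medium were preincubated for 30 min at 25 °C and 750 rpm and then given 100 nM N-acetylchitooctaose, a chitin oligosaccharide that acts as an elicitor, or water for 2 h. Each of the 4 deposited arrays was hybridised with chitin-treated RNA in one dye and water-treated RNA of the same line in the other. Each line had 1 array with chitin in Cy5 and 1 colour swap with chitin in Cy3.

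The authors' deposited scanner files come from Agilent Feature Extraction with a protocol for 2-colour expression arrays, per the file headers. They hold the mean and median pixel intensity of each spot in Cy3 and Cy5, the median intensity of the local background, and processed intensity values that the software had background-subtracted and dye-normalized, per the file headers. Their log ratio is the log10 of Cy5 over Cy3 processed signal, per the file headers. The deposited value table of the series equals the log10 of water over chitin within 0.006 for 100% of the entries of each array, and its column medians were all 0. Its scale and direction were found in this way, and no further centring was seen. Each array carried 45151 features, of which 43224 were probe spots of 37904 distinct sequences of 60 bases. A share of 68.8% to 71.7% of probe spots was well above background in Cy3 and 77.8% to 79.6% in Cy5, by the deposited flags. Between 331 and 615 spots per array had an outlier flag and were left out, and 0 were saturated. The genome build is not given in the sources used here, so no coordinates are printed.

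Background was corrected with normexp (offset 50) on the mean signal and the local background, and each array was normalized with loess in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Spots of a sequence were averaged. Levels per channel, on a log2 scale, came from the same values after Aquantile normalization between arrays. Ratios were turned to chitin over water on every array. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene names and descriptions are those in the array files and can be old: 37200 sequences name 1 locus, 268 several and 436 none, and sequences with several or none were not used for genes. A gene is the mean over its sequences, and 22844 of 28581 loci were measured. Symbols such as OsCERK1 and CEBiP were given by locus in lists fixed before the data were examined.

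The labels name no separate cultures, so the array and its colour swap were taken as 1 replicate per line. No p-value across conditions is therefore a main result, and the number of arrays limits the precision. A probe or gene met the criterion, and is called higher or lower, when both arrays differed by at least 2-fold in one direction and at least 1 channel was well above background on both arrays of a line. Values are log2 ratios unless a fold is named, and the error after ± is the distance of either array from the mean of the pair. Differences between lines were taken within one dye orientation. Where the dim side was not well above background on any array of a line, a fold is a lower bound, set against the higher of the lowest signal well above background and the probe's own signal on each array. The opposite-dye control was the number of probes at least 2-fold apart in opposite directions on the 2 arrays.

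Gene lists numbered 24, fixed before the data were examined by locus and by patterns on descriptions. They cover chitin receptors and early signalling, diterpenoid phytoalexin synthesis, the plastidial isoprenoid pathway, phenylpropanoid and lignin synthesis, shikimate and aromatic amino acid synthesis, WRKY factors, pathogenesis-related proteins, calcium signalling, respiratory burst and peroxidases, ubiquitin ligases, receptor-like and wall-associated kinases, jasmonate synthesis and JAZ repressors, ethylene synthesis and ERF factors, glutathione S-transferases, UDP glycosyltransferases, cytochrome P450 enzymes, ribosomal proteins, histones, cyclins and DNA replication, cell wall loosening, heat shock proteins, photosynthesis genes, seed storage genes and control genes. The pattern for ubiquitin ligases missed the spelling of the U-box genes in the files, so that list has 6 genes on the array, of which EL5 and 4 RING-H2 genes were measured. A total of 460 loci matched by pattern were left out because their descriptions named another protein, 378 of them cyclin-like F-box proteins. That rule was fixed with the lists, but the patterns that apply it were chosen once the descriptions in the files had been read. Each list median was placed among the medians of 10000 random lists of the same size drawn in 20 intensity bins, and a list stands apart below percentile 2.5 or above 97.5. This describes these arrays and is not a test across cultures.

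Named genes followed a rule fixed at the same time: OsCERK1 and CEBiP, the 12 highest and 6 lowest genes in vector control cells, the 6 highest and 4 lowest in RNAi cells, the 8 largest positive and 4 largest negative differences, the 6 genes that met the criterion in one direction in both lines with the largest smaller ratio of the 2, the 6 highest and 6 lowest in water, and up to 4 members per list with the largest vector control ratio. Outside the receptors and the list members, only described genes were named. Genes named beyond this rule are said to be chosen after their values were seen.

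Alternatives were no background correction, a normexp offset of 16, processed signals, median pixel signals, median centring, the deposited value table, other filters on dim probes, limits of 1.5-fold and 3-fold, single arrays, single dyes, other normalization between arrays, limma on the 4 arrays as separate samples with and without a dye coefficient, and camera set tests. Limma and camera p-values with Benjamini-Hochberg adjustment measure only the spread between arrays. Camera with an estimated correlation rests on the few residual degrees of freedom that 4 arrays leave. A lack of calls there is therefore not evidence against a list. Centring on ribosomal proteins, untrimmed lists, the chitin channels, probes bright in all 8 channels and probes with similar water levels were chosen after seeing the data. On simulated data with known changes, the 2-array criterion recovered 94.0% of 50 probes changed 3-fold and 28.0% of 50 changed 2-fold in the vector control comparison, with 0 false calls among 29108 probes. For RNAi cells it recovered 96.2% of 26 probes at 3-fold with 1 false call among 29558, and for the difference 95.8% of 24 with 14 false calls among 30408. The simulation changed 200 probes, as many up as down, with noise from the vector control arrays for both lines. It therefore cannot show how scaling affects data in which most changes go up.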

Results

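Transcript levels were measured on 4 two-colour oligonucleotide arrays, 2 for vector control cells and 2 for OsCERK1 RNAi cells, each setting cells given chitin octamer for 2 h against cells of the same line given water. The comparison asks how far the chitin response of cultured rice cells depends on OsCERK1, a receptor kinase with LysM domains. Ratios of the array and its colour swap correlated across probes with r = 0.946 in vector control cells and 0.780 in RNAi cells, and genes are not independent replicates. The median error of a probe was 0.08 in each line, and 0 probes were at least 2-fold apart in opposite directions on the 2 arrays of either line. All 4 arrays lay on 1 slide, with the lines at different positions, and each line stands for 1 replicate throughout.

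OsCERK1 (Os08g0538300) was lower in the RNAi cells in every channel. In water its level was 11.35 ± 0.18 in vector control and 9.38 ± 0.16 in RNAi cells, a difference of -1.97 ± 0.34, or 3.92-fold lower. In chitin the levels were 12.59 ± 0.20 and 9.94 ± 0.11, a difference of -2.65 ± 0.30, or 6.27-fold lower. OsCERK1 itself was 1.24 ± 0.01 higher after chitin in vector control cells and 0.56 ± 0.05 higher in RNAi cells, where it missed the 2-fold criterion. CEBiP (Os03g0133400), the LysM protein that binds chitin oligosaccharides at the rice plasma membrane, was also lower in RNAi cells, by 2.69-fold in water (-1.43 ± 0.10) and 3.51-fold in chitin (-1.81 ± 0.02). Its chitin response was 0.92 ± 0.01 in vector control and 0.54 ± 0.09 in RNAi cells, under 2-fold in both. Each gene was read by 1 probe sequence, well above background in all 8 channels, and whether the OsCERK1 probe lies inside the interference construct is not given in the sources used here.

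**Figure D1:**
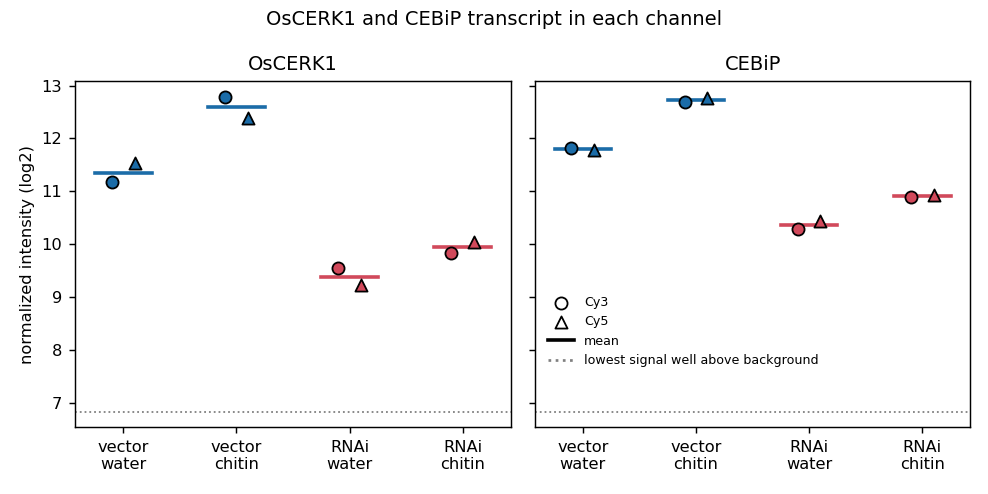
Normalized log2 intensity of OsCERK1 and CEBiP in each of the 8 channels, with circles for Cy3, triangles for Cy5, bars for the mean of both and a dotted line at the lowest signal well above background. OsCERK1 averaged 11.35 and 12.59 in vector control cells given water and chitin, against 9.38 and 9.94 in RNAi cells.

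In vector control cells the genes with the highest ratios after chitin were germins and germin-like proteins, a cupin family that holds oxalate oxidases and other cell wall proteins. Os02g0491600 was 63.7-fold higher (5.99 ± 0.15), and the germin-like genes Os12g0155000 and Os12g0154900 were 5.62 ± 0.18 and 5.49 ± 0.33 higher. Os08g0189900, Os08g0190100, Os08g0189500 and Os08g0189600, all germin-like genes of chromosome 8 by their locus names, were 5.41 ± 0.00, 5.15 ± 0.03, 4.90 ± 0.26 and 4.78 ± 0.27 higher. They were followed by a patatin-like protein, of a family of lipid acyl hydrolases (Os08g0476900, 4.70 ± 0.19), a gene described as BABY BOOM, the name of an AP2-type transcription factor (Os08g0442400, 4.66 ± 0.14), and a membrane attack complex and perforin domain protein (Os06g0251100, 4.58 ± 0.10). A harpin-induced protein (Os01g0736500) reached 4.47 ± 0.36 and an AAA ATPase (Os03g0114400) 4.47 ± 0.15. The water channel was well above background on 1 of 2 vector control arrays for Os02g0491600, Os12g0155000, Os12g0154900 and Os08g0476900, so the size of these ratios is the least certain.

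The lowest ratios in vector control cells were those of a calcium-binding protein (Os02g0606500, -2.92 ± 0.02), an AUX1-like protein of the auxin influx carrier family (Os10g0147400, -2.71 ± 0.05) and enzymes acting on cell wall polymers. Among these were a pectate lyase (Os04g0137100, -2.53 ± 0.05), an endo-beta-1,4-glucanase (Os05g0212300, -2.42 ± 0.16) and a family 16 glycoside hydrolase (Os09g0395600, -2.31 ± 0.25). A CRAL-TRIO domain protein (Os04g0561200) stood at -2.37 ± 0.06. Altogether 1964 genes were higher and 437 lower among 21868 measured, or 2489 and 541 of 29108 probes. Higher probes made up 82.1% of those calls, against 64.9% with the scanner software's processed signals, 65.3% with the deposited value table and 97.7% with each array centred on its ribosomal protein genes.

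**Figure D2:**
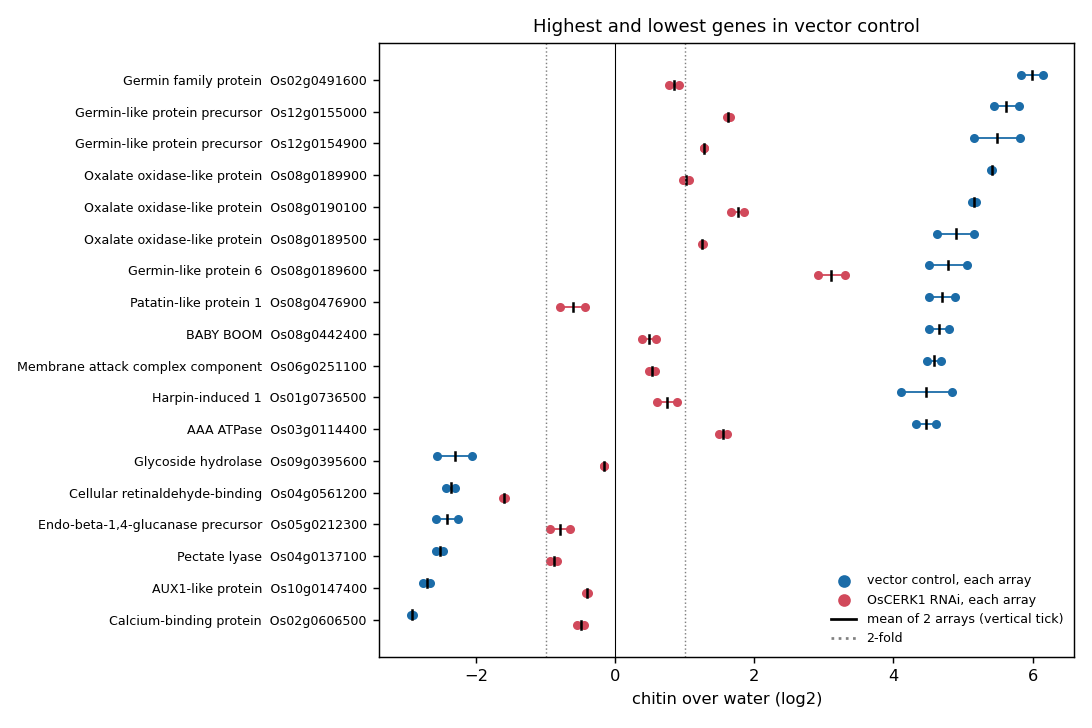
Chitin over water log2 ratio of the 12 highest and 6 lowest named genes of vector control cells, with each array as a point, the mean as a tick, and OsCERK1 RNAi cells in red. Os02g0491600 stood at 5.99 in vector control and 0.85 in RNAi cells, and Os02g0606500 at -2.92 and -0.50.

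Enzymes of phenylpropanoid and lignin synthesis, which lead from phenylalanine to lignin and phenolic compounds, were the list with the highest median in vector control cells. Of 34 measured members 18 were higher and 0 lower, with a median of 1.39, above all 10000 random lists. The phenylalanine ammonia-lyase genes Os05g0427400 and Os02g0626600, for the first step, were 3.88 ± 0.05 and 3.81 ± 0.18 higher, cinnamate 4-hydroxylase (Os02g0467600) 3.37 ± 0.01 and 4-coumarate-CoA ligase (Os08g0448000) 3.33 ± 0.01. The shikimate and aromatic amino acid list, which supplies phenylalanine, had 14 of 38 members higher and 0 lower, with a median of 0.36. In it a prephenate dehydratase (Os04g0406600) was 2.73 ± 0.13 higher, a shikimate kinase (Os02g0749300) 2.40 ± 0.13 and a chorismate mutase (Os08g0441600) 2.23 ± 0.01. Jasmonate synthesis and JAZ repressors had a median of 1.04 and 13 of 28 higher, including allene oxide synthase OsAOS1 (Os03g0767000, 3.39 ± 0.03), a lipoxygenase (Os03g0738600, 2.64 ± 0.01) and the ZIM domain genes Os10g0391400 (3.49 ± 0.10) and Os10g0392400 (2.66 ± 0.25). Set tests that treat arrays as separate samples measure only the spread between arrays, and in camera adjusted p = 0.154 with an estimated correlation for phenylpropanoid synthesis, 0.324 for shikimate synthesis and 0.184 for jasmonate. Limma called 28 of 34 phenylpropanoid genes over all genes and 28 adjusted over the list alone, and 25 and 25 of 28 jasmonate genes.

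Among WRKY transcription factors, a plant family with many members that respond to pathogens, 22 of 53 were higher and 0 lower, with a median of 0.87. OsWRKY28 (Os06g0649000) stood at 4.11 ± 0.06 and the gene described as WRKY 70 (Os05g0474800) at 4.04 ± 0.04. Probes of the genes described as WRKY 24 (Os01g0826400, 3.82 ± 0.03) and WRKY 42 (Os02g0462800, 3.24 ± 0.03) differed by more than 1 in size. Ethylene synthesis and ERF factors had a lower median of 0.16, with 12 of 64 higher and 3 lower, led by the ERF-type genes Os10g0562900 (3.94 ± 0.14) and Os04g0547600 (3.14 ± 0.01). Of 82 pathogenesis-related proteins 31 were higher and 2 lower (median 0.48), among them RSOsPR10 (Os03g0300400, 3.94 ± 0.00), the chitinases Os10g0543400 (3.35 ± 0.06) and Os11g0701400 (3.12 ± 0.04) and a PR1 protein (Os07g0127700, 3.03 ± 0.05). Respiratory burst and peroxidase genes had 19 of 80 higher and 2 lower (median 0.23), led by the peroxidases Os03g0234500 (4.46 ± 0.07) and Os05g0135400 (3.40 ± 0.01). With an estimated correlation between genes in camera, adjusted p = 0.154 for WRKY factors, 0.203 for pathogenesis-related proteins and 0.283 for both ERF factors and peroxidases. Limma called 62 of 82 pathogenesis-related genes over all genes and 63 adjusted over the list alone, and 36 and 38 of 52 WRKY genes.

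Of 14 chitin receptors and early signalling genes 2 were higher, OsMPK3 (Os03g0285800, 2.20 ± 0.05), a mitogen-activated protein kinase, and OsCERK1, with a list median of 0.53 at percentile 99.3. OsLYP4 (Os09g0452200, -1.04 ± 0.09) and OsRac1 (Os01g0229400, -0.94 ± 0.01), a small GTPase, had negative ratios and did not meet the criterion. Receptor-like and wall-associated kinases had 22 of 77 higher and 3 lower (median 0.44), and calcium signalling proteins 36 of 153 higher and 3 lower (median 0.29). With an estimated correlation adjusted p = 0.412 for the receptor list, 0.154 for receptor-like kinases and 0.203 for calcium signalling. Examples were the receptor-like kinases Os07g0550400 (2.42 ± 0.08) and Os07g0541400 (2.31 ± 0.01), a calmodulin (Os12g0603800, 3.63 ± 0.00) and a calcium-dependent protein kinase (Os03g0688300, 3.03 ± 0.16). EL5 (Os02g0559800), a RING-type ubiquitin ligase known from elicitor-treated rice cells, was 3.98 ± 0.15 higher, and a RING-H2 protein (Os12g0596200) stood at -1.88 ± 0.02. The measured members of the list meant for ubiquitin ligases were EL5 and 4 RING-H2 genes, of which 1 was higher and 1 lower (median 0.57, percentile 94.1), and the list includes none of the U-box genes.

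Of the enzyme classes of secondary metabolism, UDP glycosyltransferases had 15 of 95 higher and 2 lower (median 0.22) and cytochrome P450 enzymes 23 of 137 higher and 5 lower (median 0.09), and both stood above their random lists (adjusted p = 0.203 and 0.459 with an estimated correlation). Diterpenoid phytoalexin synthesis did not stand apart (median 0.16, percentile 92.2), although 3 of 13 members were higher: the transcription factor DPF (Os01g0196300, 2.24 ± 0.03), momilactone synthase OsMAS (Os04g0179200, 2.19 ± 0.01) and CYP99A2 (Os04g0180400, 1.34 ± 0.12). Glutathione S-transferases had 4 of 47 higher, led by Os01g0372400 (3.54 ± 0.03), with a median of 0.10 at percentile 91.0. None of the 7 measured genes of the plastidial isoprenoid pathway, the source of diterpene precursors, met the criterion (median 0.16), and 3 of 9 seed storage genes were higher, all described as glutelins (Os12g0283400, 2.55 ± 0.05; Os03g0188500, 2.16 ± 0.05; Os08g0482300, 1.31 ± 0.25), with a list median of 0.20 at percentile 87.1.

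Ribosomal proteins, needed for growth, had a median of -0.49, below all 10000 random lists, with 8 of 291 lower and 0 higher, led by an L1 family gene (Os04g0500200, -1.69 ± 0.17) and L30 (Os01g0812800, -1.39 ± 0.01). Cyclins and DNA replication genes had a median of -0.37 with 3 of 48 lower, among them PCNA (Os02g0805200, -1.14 ± 0.12), but 0.12 with each array centred on ribosomal proteins. With an estimated correlation adjusted p = 0.0645 for ribosomal proteins and 0.154 for cyclins and DNA replication. Expansins and related cell wall genes, which loosen walls in growing cells, had 7 of 38 lower and 3 higher, including OsEXPA5 (Os02g0744200, -1.87 ± 0.04) and a beta-expansin (Os04g0530100, -1.77 ± 0.06), with a median of 0.02. Medians of histones (0.02), heat shock proteins (-0.03), photosynthesis genes (0.01) and control genes (-0.06) lay within their random lists, and each of these and the cell wall median changed sign under at least 1 scaling. Within the control list Actin 12 (Os01g0866100, 1.32 ± 0.28) was higher and a beta tubulin (Os03g0105600, -1.29 ± 0.18) lower.

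Across the 24 lists 12 lay above and 2 below their random lists in vector control cells, and the largest error of a list median was 0.09. With lists restricted to the loci named one by one, 4 lay above and 0 below. With arrays treated as separate samples, camera with a preset correlation called 11 lists, and with an estimated correlation 0. The estimate was -0.00065 for ribosomal proteins and -0.014 for phenylpropanoid synthesis, so correlation between genes did not remove those calls. With so few arrays that setting has little power. The preset correlation did not call chitin receptors (camera adjusted p = 0.157), ERF factors (0.0902) or P450 enzymes (0.0889), although these lists stood apart. For ribosomal proteins, the list with the smallest p, limma called 240 of 287 genes over all genes and 253 adjusted over the list alone.

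In OsCERK1 RNAi cells fewer genes met the criterion: 495 higher and 23 lower of 22204. The highest was a heavy metal transport and detoxification domain gene (Os02g0585200, 3.91 ± 0.11), followed by genes described as a resistance protein candidate (Os12g0608700, 3.23 ± 0.09), germin-like protein 6 (Os08g0189600, 3.11 ± 0.20), a transfactor-like protein (Os02g0168200, 3.10 ± 0.16), RPP17-1 (Os01g0841700, 3.09 ± 0.12) and a matrixin-type peptidase (Os06g0239100, 2.99 ± 0.08). The same 6 genes had the largest values of the smaller of their ratios in both lines, with vector control ratios of 3.79 ± 0.20, 3.52 ± 0.08, 4.78 ± 0.27, 3.55 ± 0.24, 4.06 ± 0.14 and 4.16 ± 0.03 in that order. The lowest were a pepsin-type peptidase (Os10g0537800, -2.34 ± 0.15), an FAD-dependent oxidoreductase (Os08g0114300, -1.86 ± 0.30), a subtilase (Os02g0269600, -1.75 ± 0.18) and a leucine-rich repeat glycoprotein (Os11g0514500, -1.66 ± 0.15). For Os10g0537800, Os08g0114300 and Os11g0514500 the chitin channel was well above background on 1 of 2 RNAi arrays. By probe, 610 were higher and 29 lower of 29558, and higher probes made up 95.5% of the calls, against 87.4% (870 and 125 probes) with the processed signals and 87.6% (856 and 121) with the deposited value table.

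WRKY factors and pathogenesis-related proteins had the highest medians among the RNAi lists that stood apart. WRKY factors had 8 of 53 higher (median 0.27), with OsWRKY28 (Os06g0649000) at 2.24 ± 0.11 and WRKY 24 (Os01g0826400) at 2.58 ± 0.04. Pathogenesis-related proteins had 13 of 83 higher (median 0.25), with the chitinases Os10g0543400 at 2.16 ± 0.00 and Os11g0701400 at 1.94 ± 0.02. For both lists adjusted p = 0.231 with an estimated correlation, and limma called 22 of 52 WRKY genes over all genes and 24 adjusted over the list alone. Phenylpropanoid synthesis had 2 of 34 higher and a median of 0.08, within its random lists (percentile 96.3), and the PAL genes Os05g0427400 and Os02g0626600 stood at -0.08 ± 0.03 and 0.07 ± 0.05. Jasmonate genes had 1 of 28 higher (median 0.17, percentile 99.8), and receptor-like kinases 8 of 77 (0.17). Calcium signalling had 8 of 154 higher (0.09), peroxidases 2 of 80 (0.09), UDP glycosyltransferases 4 of 94 (0.11), ERF factors 4 of 63 (0.12) and P450 enzymes 11 of 136 (0.04, or -0.005 without the first RNAi array). Ribosomal proteins (-0.15), histones (-0.25), cyclins and DNA replication (-0.14), heat shock proteins (-0.06) and photosynthesis genes (-0.10) lay below their random lists. The last 3 had positive medians of 0.01, 0.10 and 0.06 when arrays were centred on ribosomal proteins. Few members met the criterion: in that order 0 of 288, 0 of 43, 0 of 51, 0 of 123 and 1 of 40 were lower. Of the heat shock genes 2 were higher. Limma called 15 of 287 ribosomal genes over all genes and 1 adjusted over the list alone. On the single RNAi arrays the heat shock median was -0.02 and -0.05. Camera with the preset correlation did not call heat shock proteins (adjusted p = 0.299) or P450 enzymes (0.111). It did call phenylpropanoid synthesis (0.0468), which lay within its random lists. In camera, 13 of the 24 lists were called with a preset and 0 with an estimated correlation, where adjusted p = 0.130 for ribosomal proteins, the smallest, 0.231 for receptor-like kinases, calcium signalling, ERF factors, UDP glycosyltransferases, histones and cyclins, 0.266 for jasmonate and between 0.359 and 0.446 for peroxidases, photosynthesis, P450 enzymes and heat shock proteins.

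The remaining RNAi lists did not stand apart: chitin receptors (0.15), shikimate synthesis (0.08), EL5 and the RING-H2 genes (0.07), glutathione S-transferases (0.02), seed storage genes (0.09), cell wall loosening (0.03, or -0.12 with probes well above background in both channels), control genes (-0.04), diterpenoid synthesis (-0.06) and the plastidial isoprenoid pathway (-0.08). Of these, glutathione S-transferases turned negative with the processed signals, and control genes and both terpenoid lists positive with centring on ribosomal proteins. On the single RNAi arrays chitin receptors stood at 0.03 and 0.16, and shikimate synthesis at 0.14 and 0.02.

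**Figure D3:**
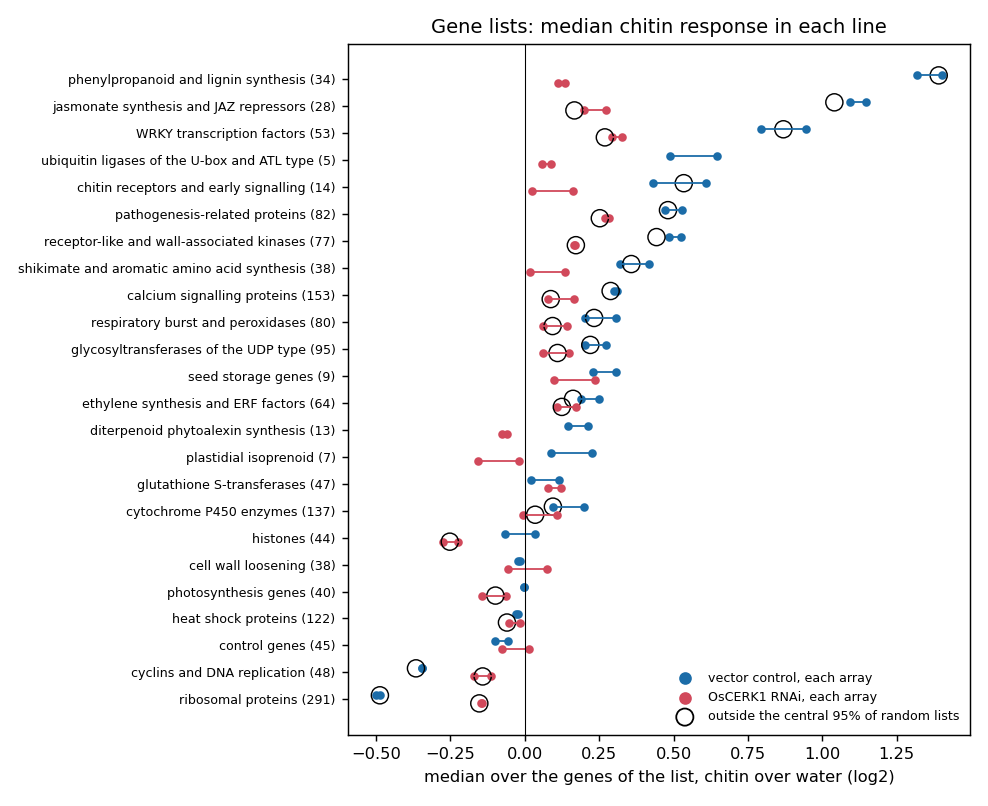
Median chitin over water log2 ratio of each gene list on each array, with the number of genes measured in vector control cells in brackets. Rings mark the median of gene means, which need not lie between the 2 array medians, where it fell outside the central 95% of random lists; for phenylpropanoid synthesis the vector control stood at 1.39 and the RNAi cells at 0.08.

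Of the 2465 probes higher in vector control cells and measured in both lines, the median ratio was 1.65 in vector control and 0.61 in RNAi cells. A share of 20.7% (511 probes; exact binomial 95% interval 19.1% to 22.4%, counting error only) still met the criterion in RNAi cells, and 92.5% kept the same sign. The slope through 0 of RNAi on vector control ratios was 0.358. OsWRKY28 (Os06g0649000) kept 2.24 of 4.11, EL5 (Os02g0559800) 1.73 of 3.98, the chitinase Os10g0543400 2.16 of 3.35, and allene oxide synthase (Os03g0767000) 0.62 of 3.39. Of the 533 lower probes the medians were -1.31 and -0.40, and 12 (2.25%, interval 1.17% to 3.90%) still met the criterion, with a slope of 0.280. Without either RNAi array that share was 3.93% or 4.27%. By gene, 419 were higher in both lines and 9 lower in both, 1538 were higher and 426 lower in vector control cells alone, and 74 were higher and 7 lower in RNAi cells alone by the criterion. A further 7 were higher in vector control and lower in RNAi cells, among them OsMAS (Os04g0179200) and the P450 Os01g0561600, and 2 the reverse, the transferase Os03g0745200 and Os08g0127800, the latter chosen after its values were seen. By size of the vector control ratio, 150 of 1305 higher genes between 1 and 2 still met the criterion in RNAi cells. Between 2 and 3 these were 157 of 463, and above 3 they were 112 of 196. The median fraction of the ratio kept was 0.362, 0.372 and 0.335. It varied widely between genes, with 10th to 90th percentiles of 0.04 to 0.77, 0.04 to 0.68 and -0.02 to 0.66. Across higher probes the ratios of the 2 lines correlated with r = 0.404.

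**Figure D4:**
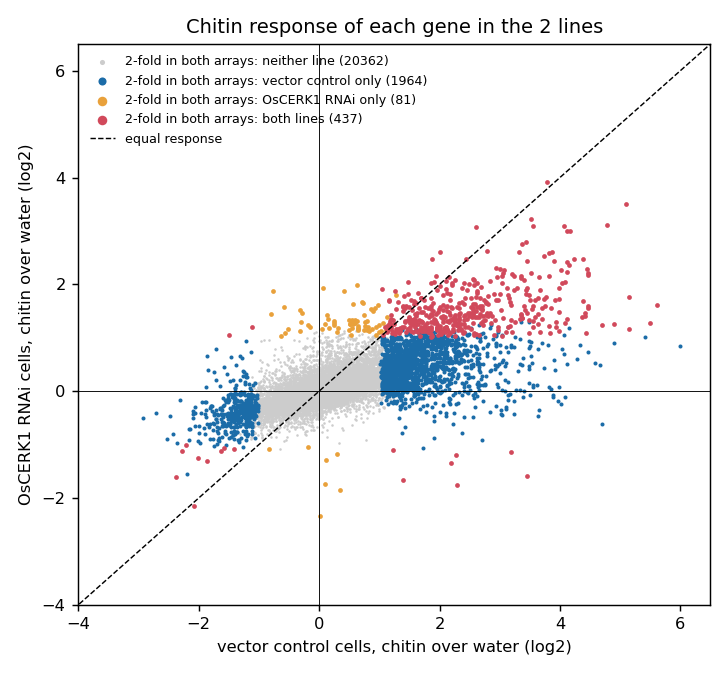
Chitin over water log2 ratio of each gene in vector control cells (horizontal) and OsCERK1 RNAi cells (vertical), coloured by the lines in which both arrays differed by at least 2-fold; the dashed line marks equal response. In vector control cells alone 1538 genes were higher and 426 lower, and 419 were higher and 9 lower in both lines.

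The difference in response between the lines met the criterion for 1023 genes with a larger and 230 with a smaller ratio in vector control cells, of 22844. For the patatin-like gene Os08g0476900 the chitin channel was not well above background in RNAi cells, so only a bound holds: its level after chitin was at least 24.5-fold lower than in vector control. Other large differences were those of the germin Os02g0491600 (5.14 ± 0.23), the germin-like Os08g0189900 (4.39 ± 0.04), a P450 (Os01g0561600, 4.31 ± 0.02), an aminotransferase (Os01g0928700, 4.26 ± 0.29), Os12g0154900 (4.22 ± 0.33), the gene described as BABY BOOM (Os08g0442400, 4.17 ± 0.04) and a plastocyanin-like protein (Os06g0681200, 4.16 ± 0.12). In the other direction stood a beta-amylase (Os10g0465700, -2.50 ± 0.05), the calcium-binding protein Os02g0606500 (-2.42 ± 0.07), a transferase (Os03g0745200, -2.32 ± 0.09) and the AUX1-like Os10g0147400 (-2.30 ± 0.04). By probe 1267 and 298 of 30408 met the criterion, 81.0% of them larger in vector control cells, against 66.0% with the processed signals, 66.1% with the deposited value table and 95.8% with centring on ribosomal proteins. With arrays as separate samples, limma called 1451 and 364 probes at 2-fold with adjusted p under 0.05.

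Phenylpropanoid synthesis had the largest median difference (1.03, with 15 of 34 larger in vector control and 0 smaller), followed by jasmonate (0.84, 11 of 28). Diterpenoid phytoalexin synthesis (0.43, 4 of 13) and WRKY factors (0.40, 12 of 52) also lay above their random lists, with OsMAS (Os04g0179200) at 3.54 ± 0.08 and OsWRKY28 (Os06g0649000) at 1.86 ± 0.06. So did chitin receptors (0.39), histones (0.24), pathogenesis-related proteins (0.23), shikimate synthesis (0.21), calcium signalling (0.19), peroxidases (0.15), receptor-like kinases (0.15), UDP glycosyltransferases (0.11) and P450 enzymes (0.10). The pathogenesis-related median was -0.12 with loci named one by one. Ribosomal proteins (-0.33), cyclins and DNA replication (-0.21) and cell wall loosening (-0.18) lay below, the last 2 at 0.12 and 0.15 with centring on ribosomal proteins. The other 8 lists did not stand apart: ERF factors (0.10), the plastidial isoprenoid pathway (0.31), EL5 and the RING-H2 genes (0.19), seed storage (0.20), photosynthesis (0.08), glutathione S-transferases (0.02), heat shock (0.01) and control genes (-0.06). In camera 13 lists were called with a preset and 0 with an estimated correlation, where adjusted p = 0.0807 for ribosomal proteins, the smallest, 0.168 for phenylpropanoid synthesis, 0.198 for jasmonate, WRKY factors and cyclins, 0.321 for diterpenoid and shikimate synthesis, pathogenesis-related proteins, calcium signalling, peroxidases and receptor-like kinases, and between 0.359 and 0.505 for chitin receptors, UDP glycosyltransferases, cell wall loosening, histones and P450 enzymes. Camera with the preset correlation did not call chitin receptors (adjusted p = 0.154), UDP glycosyltransferases (0.154) or P450 enzymes (0.263), although these lists stood apart. Limma called 24 of 34 phenylpropanoid genes over all genes and 26 adjusted over the list alone, and 20 and 24 of 28 jasmonate genes.

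Without chitin the lines also differed: in water 1341 genes were higher and 1276 lower in RNAi cells, of 22844. An alpha-amylase (isozyme 3B, Os09g0457600), a starch-degrading enzyme, was 103-fold higher (6.69 ± 0.19), a UDP-glycosyltransferase (Os05g0552700) 48.6-fold and a dicarboxylate cotransporter (Os09g0484900) 36.5-fold higher (5.19 ± 0.24). Os01g0290300, a BED finger gene, Os08g0128700, a MATH domain gene, and Os05g0270500, related to ribonuclease P, were not well above background in vector control cells and were at least 54.4-fold, 40.1-fold and 32.2-fold higher in RNAi cells. The lowest in RNAi cells were a thionin (Os02g0629800, -5.44 ± 0.10), of a family of small antimicrobial peptides, a thioredoxin (Os07g0190800, -4.72 ± 0.13), a pepsin-type peptidase (Os09g0452400, -4.50 ± 0.21), an Ole e 1 domain protein (Os05g0531200, -4.34 ± 0.14), the endoglucanase Os05g0212300 (-4.32 ± 0.20) and a lipid transfer protein (Os01g0691100, -4.18 ± 0.08). The vector control level of Os05g0552700 and the RNAi level of Os02g0629800 were each well above background on 1 of 2 arrays.

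Diterpenoid phytoalexin genes were lower in RNAi cells in water, with 7 of 13 lower, 0 higher and a median of -1.16 below all random lists, including CYP99A2 (Os04g0180400, -2.16 ± 0.16), OsMAS (Os04g0179200, -1.62 ± 0.28) and DPF (Os01g0196300, -1.24 ± 0.01). Pathogenesis-related proteins had 16 of 82 lower and 3 higher (-0.45), receptor-like kinases 10 of 77 lower and 1 higher (-0.41), cell wall loosening 7 of 38 lower and 2 higher (-0.48) and phenylpropanoid synthesis 7 of 34 lower and 1 higher (-0.31). Photosynthesis genes, kept as markers of green cells, had 14 of 40 higher and 0 lower (0.74), and histones 10 of 41 higher and 1 lower (0.58). A chlorophyll-binding protein (Os01g0720500, 4.57 ± 0.04), a photosystem II polypeptide (Os07g0141400, 3.33 ± 0.02) and the pathogenesis-related PBZ1 (Os12g0555500, -3.24 ± 0.13), chosen after their values were seen, were among the largest. The cells were kept in the dark, and seed storage genes did not stand apart (0.18, percentile 72.7). Ribosomal proteins (-0.25), peroxidases (-0.13), glutathione S-transferases (-0.18), P450 enzymes (-0.06, with -0.03 and 0.01 in the 2 dye orientations taken alone), WRKY factors (-0.12, with -0.01 and -0.07) and the plastidial isoprenoid pathway (-0.57) also lay below their random lists. Levels of the lines were compared across arrays, never on 1 array. Between arrays of 1 line 53 and 456 probes differed by at least 2-fold in mean channel level, against 4269 to 4913 between lines. This argues against variation between single arrays as the cause of those differences. The mean level includes the chitin channel, so the counts do not isolate the water difference. Line and a position effect common to both its arrays cannot be told apart.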

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

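The tests of OsCERK1 level and of CEBiP against genes of similar intensity were chosen only after their results were seen, and the other tests had predictions written before they were run. The genes and lists named first here had both arrays of one line above 0 and both arrays of the other below 0, and the difference was not tested. Values are vector control minus RNAi, in log2.

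For the P450 Os01g0561600 the difference was 4.31, for the aminotransferase Os01g0928700 4.26 and for the subtilase Os02g0269600 4.04. The phenylalanine ammonia-lyase Os05g0427400 stood at 3.96, OsMAS (Os04g0179200) at 3.54 and the leucine-rich repeat glycoprotein Os11g0514500 at 3.06. Smaller differences were those of the oxidoreductase Os08g0114300 (2.20), CYP99A2 (Os04g0180400, 1.61), a histone H4 (Os07g0549900, 1.11), the UDP-glycosyltransferase Os05g0552700 (1.07) and OsCMS (Os01g0887100, 0.37). Negative differences were those of the beta-amylase Os10g0465700 (-2.50), the transferase Os03g0745200 (-2.32), the RING-H2 gene Os12g0596200 (-1.95), the thionin Os02g0629800 (-1.60), the Ole e 1 domain gene Os05g0531200 (-1.28), the thioredoxin Os07g0190800 (-0.93) and OsDXS1 (Os05g0408900, -0.46). The patatin-like Os08g0476900 (5.31), the PR1 gene Os07g0127700 (3.48) and the peroxidase Os01g0963000 (3.21) were not well above background in the chitin channel of either RNAi array, so their sign in RNAi cells and the size of these differences are not measured. For Os08g0114300, Os11g0514500, CYP99A2 and Os02g0629800 that channel was well above background on 1 of 2 arrays. Among lists, diterpenoid phytoalexin synthesis differed by a median of 0.43 and the plastidial isoprenoid pathway by 0.31. Their RNAi medians were only -0.06 and -0.08, and both turned positive with arrays centred on ribosomal proteins. With arrays centred on ribosomal proteins, whose medians on the RNAi arrays were -0.16 and -0.15, RNAi ratios nearer 0 than these would no longer be below 0, as for Os05g0427400 (-0.08) and OsCMS (-0.09).

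The smaller chitin response of the RNAi cells was weighed against 3 explanations. A higher starting level of the chitin-induced genes would leave less room to respond. Over the 1953 genes higher in vector control cells the RNAi level in water differed by a median of only -0.087, against -1.18 in chitin. These genes were selected on the same vector control channels, which by itself pulls the water value up and the chitin value down. The water value, not raised despite that pull, argues against a higher start for these genes as a set. Among them 193 started at least 2-fold higher in water and 211 at least 2-fold lower. Compression of ratios at low signal would bring the slope near 1 for bright genes. It was 0.225, 0.387 and 0.463 from the dimmest to the brightest of 3 groups of 651 genes, so compression may add to the loss among dim genes but argues against it as the whole cause. Lower OsCERK1, at -2.65 in chitin, could explain the loss as a hypothesis. Knock-down, line and a position effect common to both arrays of a line cannot be told apart with 1 line of each kind. CEBiP was lower in the same cells, at -1.81 in chitin, so the loss cannot be credited to OsCERK1 alone.

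The water difference between the lines had r = 0.915 between both dye orientations, with 4 probes at least 2-fold apart in opposite directions. In the mean of the chitin and water channels, 53 and 456 probes differed by at least 2-fold between arrays of a line. Between lines the numbers were 4269 to 4913. The ratio of means was 5.54%, which argues against technical variation between single arrays as the cause of these differences in mean level. That level includes the chitin channel, so the counts do not isolate the water difference. The ratio sets single lines against technical noise, so line, culture and a position effect common to both arrays of a line cannot be told apart. The water difference had little linear correlation with the vector control response, r = 0.0625 over 22342 genes. Genes that responded in vector control cells still differed in water more often than others. Of 1953 higher genes, 193 stood at least 2-fold higher in RNAi cells in water and 211 lower. Of 433 lower genes the counts were 12 and 142, against 992 and 923 of 19248 genes that were neither. As a set, the 433 genes lower in vector control cells stood at a median of -0.59 in RNAi cells in water and 0.34 in chitin. They were selected on the same vector control channels, which by itself pulls the water value down and the chitin value up. Whether part of their smaller response reflects a lower start is therefore left open. Over all settings, among them probes with similar water levels, the slope for lower probes did not exceed 0.347. That argues against a lower start as the whole cause.

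CEBiP, lower in RNAi cells, was at percentile 3.52 of the water differences of 1136 genes of similar intensity, with 40 genes lower still, and OsCERK1 was at percentile 1.85, with 21 lower. The CEBiP value lay inside the range set for a broad difference between the lines, as most genes do by construction. The percentile therefore cannot tell a broad difference from an effect specific to CEBiP, and neither is excluded.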

How the results depend on the processing

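The 8 alternatives that centre on ribosomal proteins, keep untrimmed lists, use the chitin channels, or select probes bright in all 8 channels or with similar water levels were chosen after seeing the data, and all others before the data were examined. Of the values that answer a comparison, 255 stayed within their limits and 105 moved, and of single gene and list values 2281 stayed, 851 moved and 8 reversed. Probes higher in vector control numbered 2230 to 2938 outside the settings given here, the OsCERK1 difference in chitin -3.03 to -2.35, and the slope for higher probes ranged from 0.326 to 0.399 over all settings. The cause was not tested unless one is named.

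With processed signals, lower probes numbered 1466 in vector control, 125 in RNAi cells and 794 in the difference, against 541, 29 and 298. For higher probes the RNAi median was 0.69, the share still meeting the criterion 24.7% and the slope 0.326, and the lower median was -0.45. OsCERK1 in water was -2.51, and 4563 probes were lower in water. The deposited value table gave 1418, 121 and 784 lower probes, 0.70, 24.6%, 0.326 and -0.45. Median centring gave 1538 higher and 352 lower probes in vector control and 352 and 15 in RNAi cells, medians of 0.72 and -0.48 and a share of 18.2%. Median shifts of all probes were -0.12 in vector control with processed signals and with the deposited table.

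At 3-fold, by construction fewer probes passed: 1197 higher and 82 lower in vector control, 153 and 4 in RNAi cells, 456 and 47 in the difference and 611 and 694 in water. Medians were 0.85 and -0.57, the share 10.7% and the lower slope 0.303. At 1.5-fold more passed: 4420 and 2083, 1618 and 201, 2936 and 1348, and 4025 and 3464 in that order, with medians of 0.42 and -0.29 and shares of 30.0% and 6.08%.

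Centring on ribosomal proteins sets their median to 0 and so raises all others: 4870 higher and 115 lower probes in vector control, 15 lower in RNAi cells, 2419 and 107 in the difference, and 1 list below its random lists in vector control. The cyclin median became 0.12 in vector control, 0.014 in RNAi cells and 0.12 in the difference, the cell wall difference 0.15, and in RNAi cells heat shock became 0.10 and photosynthesis 0.057. With lists of single loci only, 4 lists lay above and 0 below in vector control, 3 and 0 in RNAi cells and 4 and 0 in the difference, where the pathogenesis-related median was -0.12. Camera with an estimated correlation, which has little power with so few arrays, called 0 above and 0 below in each.

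The lower RNAi median, -0.40 in the main result, was -0.39 with no background correction, -0.41 with offset 16 and -0.38 with median pixels. With both channels well above background the higher median was 0.65 and the slope 0.384. With 2-fold in the mean the values were 0.56, 22.4% and -0.37. Probes selected on the first vector control array and measured on the second gave 0.54, 18.04%, -0.35 and a lower slope of 0.297, and the reverse 0.56, 18.6% and -0.36. Probes bright in all 8 channels gave 0.67, 23.1%, slope 0.399 and -0.40. Probes with similar water levels gave 19.1%, slope 0.380, -0.42 and a lower slope of 0.340. All probes gave a slope of 0.347, and 2673 probes were lower in the chitin channels.

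Leaving out each array in turn, lower probes numbered 713 to 849 with 1 vector control array and 50 to 51 with 1 RNAi array, since 1 array is easier to pass than 2. The higher median ranged from 0.54 to 0.62, its share from 18.1% to 26.3%, the lower median from -0.40 to -0.35, its share from 1.44% to 4.27% and its slope from 0.267 to 0.281. The P450 median in RNAi cells ranged from -0.0046 to 0.11.

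At 2-fold and adjusted p under 0.05, limma with a dye coefficient (replicate block) called 2791 and 718 probes in vector control, 755 and 36 in RNAi cells and 1459 and 368 in the difference, against 2790 and 718, 755 and 36, and 1451 and 364 without it. With no fold limit the block moved the counts far more: 11193 higher and 10430 lower probes in vector control against 8071 and 6655, 7322 and 6493 in RNAi cells against 3139 and 1098, and 8373 and 7200 in the difference against 3826 and 2189. The replicate number stands for dye orientation and pairs no cultures. No paired analysis was possible because the labels name no pairs of cultures. A block for slide or scan was not run, since all 4 arrays lay on 1 slide. Median signal over background was 6.33 to 7.53 in Cy3 and 16.7 to 18.4 in Cy5, which limits ratios of dim genes, and leaving out the filter on dim probes added no probe to any count.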

Other observations

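Protein families grouped by the words of their descriptions after seeing the data, 323 of them with at least 8 genes, gave further groups in which vector control cells responded to chitin: 13 lay above and 7 below all of their random lists. U-box genes, which encode ubiquitin ligases, had 19 of 40 members higher and 0 lower, with a median of 0.99, against 8 of 40 and 0.40 in RNAi cells. Os03g0240600, chosen after its values were seen, was 4.46 ± 0.13 higher in vector control and 2.17 ± 0.05 in RNAi cells. The germin family had 8 of 10 higher with a median of 4.25, against 5 of 10 and 1.06 in RNAi cells. PDR-type ABC transporters (the pdr abc family), not among the 13, had 7 of 14 higher with a median of 0.73, against 3 of 14 and 0.17 in RNAi cells. Os02g0208300, also chosen after its values were seen, stood at 4.08 ± 0.16 in vector control and 2.05 ± 0.11 in RNAi cells.

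In water, 5 of the families lay above and 6 below all of their random lists in RNAi cells against vector control cells. Alpha-amylase genes (the alpha amylase family), which degrade starch, had 5 of 9 members higher and 2 lower in RNAi cells, with a median of 1.20. Os02g0765600 and Os02g0765400, chosen after their values were seen, stood at -3.59 ± 0.07 and -3.62 ± 0.02. Genes of the photosystem ii family had 6 of 13 higher and 0 lower (0.94). The other families above were histone h (11 of 42 higher and 1 lower, 0.58), cyclin f (28 of 300 higher and 9 lower, 0.31) and tpr (20 of 317 higher and 2 lower, 0.25). The cyclin f name is cut from cyclin-like F-box, the kind of protein that was left out of the cyclin list. Of the families below, plant lipid transfer genes (the plant lipid family) had 10 of 33 lower and 1 higher (-0.57), basic helix genes 13 of 69 lower and 0 higher (-0.46), harpin induced genes 5 of 33 lower and 0 higher (-0.46), receptor kinase genes 9 of 46 lower and 1 higher (-0.50), s ribosomal genes 8 of 178 lower and 1 higher (-0.30) and kinase genes 50 of 463 lower and 24 higher (-0.10).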
